A study of Mus musculus with 6 samples.

How the data were processed

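RNA had been isolated from Trizol lysates as total RNA. The submitters' processing notes name STAR, HOMER and the mouse genome build mm10, without their roles, versions or order. The deposited table, made by the authors, holds FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of a library) for 28569 loci in 6 columns, 1 per library. Neither the program behind the table, its annotation, nor any scaling between libraries is stated. Loci without a gene name, 4562 in number, held 96.7% to 98.6% of the summed FPKM of a library and were left out; 911 loci carry several gene names and were kept, 747 of them among those tested, and their values cannot be assigned to a single gene.

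Values were taken as log2(FPKM + 1). Loci with at least 1 FPKM in at least 2 of the 6 libraries were tested, 11434 in all. A model with 1 mean per population was fitted to the 6 libraries in limma 3.58.1 (R 4.3.3; lmFit, contrasts, and eBayes with a trend of variance on mean), which left 3 residual degrees of freedom per locus and a prior of 3.02. Tests were two-sided, with Benjamini-Hochberg adjustment over the loci of each comparison and a threshold of adjusted p under 0.05. An exact permutation test of 2 libraries against 2 cannot give a p below 0.333 and was not used. The labels do not say whether libraries of a population came from separate cultures, so the p-values measure only the spread between these libraries. Replicates had a Pearson correlation across tested loci, which are not independent, of 0.988 in CD73-negative, 0.988 in CD73-positive and 0.984 in DN3 cells.

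The comparisons, the 28 gene lists, the tests, the rule for naming genes and most alternatives were fixed before the data were examined. Gene lists with at least 3 tested members, 26 in each comparison, were tested with camera in limma (preset correlation 0.01, Benjamini-Hochberg over the lists of a comparison). It called 10 lists for CD73-negative against DN3 (7 up, 3 down), 11 for CD73-positive against DN3 (7 up, 4 down) and 9 between the CD73 populations (3 up, 6 down). With a correlation estimated per list it called 0 in each comparison, and 0 at unadjusted p under 0.05, with lowest adjusted p 0.534, 0.551 and 0.725; fry, which tests whether the genes of a list move on balance one way, called 13, 21 and 0, and 14, 21 and 13 at unadjusted p under 0.05. Counts adjusted over the list alone come from a Benjamini-Hochberg adjustment within that list. Some lists share members, such as Ptcra in the DN3 stage, Notch target and alpha-beta lineage lists, so their results are not independent. All counts cover tested members only, such as 7 of the 14 NK and innate lymphoid markers named and 14 of the 24 gamma-delta lineage genes named.

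Named genes were Nt5e, Rag2 and Rag1; per comparison, the 10 largest rises and 10 largest falls among genes past the threshold with non-overlapping libraries, a mean of at least 5 FPKM in the higher population and an established gene symbol; and per list up to 4 members past the threshold with the largest change, or up to 2 with the smallest p where none passed. A share of these is named in the text, and 1 gene result is not reported here.

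Simulated data for comparisons with shared libraries came from the fitted variances with no difference between populations, in 100 sets. Tested on simulated data with the moderated variances and 200 changed genes, all above a log2 mean of 2, limma recovered 52.2% to 61.2% of 1.5-fold, 91.0% to 95.5% of 2-fold and 98.5% to 100% of 4-fold changes, with 3.45% to 6.18% of calls false. Far more loci were called in each measured comparison, so recovery there may differ from these rates. Depth is not stated. The smallest steps between low FPKM values put depth, relative to CD73-negative library 1, at 1.26 in CD73-negative library 2, at 1.2 and 1.06 in CD73-positive and at 0.853 and 0.918 in DN3 libraries 1 and 2. These depths rest on transcript lengths of GENCODE M21 and on the absence of further scaling.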

Results

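Gamma-delta T cells carry a T cell receptor (TCR) of gamma and delta chains and branch from alpha-beta T cells at the DN3 stage of thymocyte development. RNA sequencing of 6 libraries covered 3 mouse populations, with 2 libraries each. DN3 cells were grown from fetal liver progenitors that lack Rag2, an enzyme needed to rearrange receptor genes, and served as the starting stage. The other populations came from DN3 cells given the KN6 gamma-delta TCR and kept for 3 days on a layer of OP9 stromal cells that display its ligand. CD73, a surface ectonucleotidase, then divided them into CD73-negative cells, which retained alpha-beta potential, and CD73-positive cells, which were committed to the gamma-delta fate. The comparisons against DN3 ask what differs after DN3 cells receive the receptor and 3 days with its ligand. The comparison of the CD73 populations asks what separates uncommitted from committed cells. No population without the receptor or ligand and kept for the same time was included. Against DN3, effects of receptor, ligand, stromal layer, culture time and CD73 sort therefore cannot be told apart. Expression is given in FPKM as mean ± SD (n = 2 in every population), and differences as log2 fold change ± SE with limma's adjusted p, two-sided. A gene rose or fell where that adjusted p was under 0.05. For gene lists, counts over the list alone were adjusted within that list.

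Nt5e encodes CD73 (XLOC_026216, chr9:88327609-88372089, mm10) and measured 16.8 ± 1.15 FPKM in CD73-positive cells, 1.5 ± 0.285 FPKM in CD73-negative cells and 3.44 ± 1.47 FPKM in DN3 cells. It rose from CD73-negative to CD73-positive cells (log2 fold change 2.84 ± 0.23, adjusted p 0.00678) and from DN3 to CD73-positive cells (log2 fold change 2.04 ± 0.23, adjusted p 0.00106). It fell from DN3 to CD73-negative cells (log2 fold change -0.80 ± 0.23, adjusted p 0.0281), a call that did not pass without CD73-negative replicate 1 (adjusted p 0.06), CD73-negative replicate 2 (0.122) or DN3 replicate 2 (0.0559), or without the filter on low values (0.0654). Rag1, whose product cuts receptor genes for rearrangement (XLOC_014963, chr2:101638252-101649532, mm10), measured 47.1 ± 4.44 FPKM in DN3, 11.9 ± 3.11 FPKM in CD73-negative and 2 ± 0.666 FPKM in CD73-positive cells. Its log2 fold change from DN3 was -1.92 ± 0.22 in CD73-negative cells (adjusted p 0.00103) and -4.02 ± 0.22 in CD73-positive cells (adjusted p 0.0002), and -2.10 ± 0.22 between them (adjusted p 0.00788). Rag2 (XLOC_013895, chr2:101560781-101633525, mm10) went from 8.83 ± 2.44 FPKM in DN3 to 2.8 ± 0.824 FPKM in CD73-negative cells (log2 fold change -1.37 ± 0.22, adjusted p 0.00341) and 1.02 ± 0.158 FPKM in CD73-positive cells (log2 fold change -2.26 ± 0.22, adjusted p 0.000699). The labels do not give the Rag2 allele, so FPKM over its locus does not check the deletion. Between CD73-positive and CD73-negative cells Rag2 was -0.90 ± 0.22 (adjusted p 0.0481), which did not pass without either CD73-negative library (0.0676 and 0.26) or either CD73-positive library (0.166 and 0.147).

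The largest rises from DN3 to CD73-negative cells included several genes that TCR signals induce. Cd5, which dampens TCR signals, went from 2.81 ± 0.525 FPKM to 90.4 ± 0.234 FPKM (log2 fold change 4.59 ± 0.16, adjusted p 0.00014). Its relative Cd6 rose by 4.40 ± 0.11 (adjusted p 0.000128). Id3, an inhibitor of E proteins that gamma-delta signals induce, went from 16.1 ± 0.39 FPKM to 286 ± 12.8 FPKM (log2 fold change 4.07 ± 0.18, adjusted p 0.000221). Imprinted growth genes were among the largest falls: the locus of the imprinted RNA H19 went from 1949 ± 593 FPKM to 45.1 ± 25.9 FPKM (log2 fold change -5.49 ± 0.52, adjusted p 0.000655). Igf2 fell by 5.50 (adjusted p 0.000128). The other genes of largest rise were Tnfrsf19 (5.06 ± 0.25), Col6a2 (4.36 ± 0.43), Col6a1 (4.22 ± 0.48), Hp (4.19 ± 0.41), Cxcl12 (4.06 ± 0.70), Klrd1 (3.89 ± 0.49) and Ikzf3 (3.86 ± 0.20). Those of largest fall were Myl10 (-5.69 ± 0.20), Vwa8 (-4.34 ± 0.15), Ifitm1 (-4.32 ± 0.27), Tph1 (-3.99 ± 0.48), Dlk1 (-3.64 ± 0.14), Ndrg1 (-3.57 ± 0.29), Chrna9 (-3.50 ± 0.14) and Havcr2 (-3.49 ± 0.29). Of 11434 loci tested, 3641 rose and 2828 fell, of which 831 and 771 changed by a log2 fold change of at least 1. Leaving out 1 library at a time gave 4326 to 5900 changed loci.

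Among 23 TCR signal-induced genes, 20 rose, 2 fell and 1 did not pass (21 and 2 over the list alone), with a median log2 fold change of 1.37 and a camera adjusted p of 1.96e-05. Slamf6 rose with Cd5, Cd6 and Id3 (log2 fold change 3.80 ± 0.35, adjusted p 0.000583). With an estimated correlation between genes the adjusted p of the list was 0.534. Of 23 TCR signalling components, 5 rose, 8 fell and 10 did not pass (6 and 8 over the list alone), and the list did not pass (median -0.32, camera adjusted p 0.313). The kinase Zap70 rose (1.53 ± 0.28, adjusted p 0.00551) while its relative Syk fell (-1.42 ± 0.24, adjusted p 0.0041), as did Themis (-1.31 ± 0.08). Costimulatory and inhibitory receptors went both ways. Of the 17, 7 rose, 5 fell and 5 did not pass (8 and 5 over the list alone, median 0.27, camera adjusted p 0.622). Pdcd1, which encodes the inhibitory receptor PD-1, went from 18.6 ± 6.96 FPKM to 189 ± 8.04 FPKM (log2 fold change 3.32 ± 0.25, adjusted p 0.000389), whereas Ctla4 fell from 139 ± 0.858 FPKM to 16 ± 0.802 FPKM (log2 fold change -3.03 ± 0.13, adjusted p 0.000213).

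Genes of cell division rose almost throughout: among 24 S phase genes 24 rose, 0 fell and 0 did not pass (24 and 0 over the list alone, median 1.31, camera adjusted p 3.88e-10). Among 22 G2/M genes 21 rose, 0 fell and 1 did not pass (21 and 0 over the list alone, median 1.04, camera adjusted p 2.28e-08). Cyclin E1 (Ccne1), which starts DNA replication, went from 3.42 ± 0.368 FPKM to 30.5 ± 1.39 FPKM (log2 fold change 2.83 ± 0.09, adjusted p 0.00014). Other examples were Rrm2 (2.00 ± 0.14), Tyms (1.85 ± 0.08) and Birc5 (1.53 ± 0.08). Both lists had an adjusted p of 0.534 with an estimated correlation. Of 22 ribosome biogenesis genes, 21 rose, 0 fell and 1 did not pass (21 and 1 over the list alone, median 0.98, camera adjusted p 1.47e-06, 0.616 with an estimated correlation). Examples were Ddx21 (1.32 ± 0.17) and Nop58 (1.23 ± 0.10). Of 25 oxidative phosphorylation genes, 23 rose, 1 fell and 1 did not pass (23 and 1 over the list alone, median 0.62, camera adjusted p 4.06e-07). The largest rises were Ndufa4 (1.35 ± 0.09) and Cycs (1.31 ± 0.09). Of 23 cholesterol synthesis genes, 17 rose, 1 fell and 5 did not pass (17 and 1 over the list alone, median 0.48, camera adjusted p 0.000571), with Pmvk (1.24 ± 0.14) and Cyp51 (0.99 ± 0.12) as the largest rises. Glycolysis genes moved the other way. Of the 18, 1 rose, 13 fell and 4 did not pass (1 and 13 over the list alone, median -1.01, camera adjusted p 0.000586), with lactate exporter Slc16a3 (-2.34 ± 0.33), glucose transporter Slc2a3 (-1.79 ± 0.35) and Aldoa (-1.43 ± 0.25) among the falls. With an estimated correlation the adjusted p was 0.534 for oxidative phosphorylation, 0.65 for cholesterol synthesis and 0.652 for glycolysis genes.

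DN3 stage genes, which mark the starting stage, mostly fell. Of the 14, 2 rose, 9 fell and 3 did not pass (2 and 9 over the list alone), although the list did not pass (median -0.92, camera adjusted p 0.0551). Dntt, which adds bases at receptor junctions, fell by 2.23 (SE 0.34, adjusted p 0.00268), while the Notch ligase gene Dtx1 (2.27 ± 0.19) and Cd28 (2.00 ± 0.12) rose. The list of 12 Notch target genes split evenly, 4 rose, 4 fell and 4 did not pass (4 and 4 over the list alone, median -0.15, camera adjusted p 0.707). Myc (1.13 ± 0.18) was higher and Igf1r (-2.15 ± 0.12) lower. Of 22 T lineage transcription factors, 5 rose, 10 fell and 7 did not pass (5 and 10 over the list alone, median -0.27, camera adjusted p 0.176). Lef1 (2.13 ± 0.14) and Tox2 (1.68 ± 0.25) rose and Spib (-1.88 ± 0.26) fell. Alpha-beta lineage genes did not pass. Of the 9, 3 rose, 4 fell and 2 did not pass (3 and 4 over the list alone, median 0.12, camera direction down, adjusted p 0.753). Cd2 (3.64 ± 0.22) was the largest rise among them. This list names 14 genes, and loci without a gene name over its member Trac were left out of the test. Those loci were higher in CD73-negative cells than in DN3. Of 14 gamma-delta lineage genes tested, 5 rose, 5 fell and 4 did not pass (5 and 5 over the list alone, median 0.03, camera direction down, adjusted p 0.915). The list names 24 genes. Loci without a gene name over its members Trdc, Tcrg-C1, Tcrg-C2 and Tcrg-C4 were left out of the test. Examples of rises were Il2rb (2.52 ± 0.47) and Blk (2.06 ± 0.31), and the falls include Nt5e, the gene of the sort marker. In both of these lists the median was positive and the test pointed down.

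Effector genes had no list past the threshold: of 19 type 1 and cytotoxic genes 7 rose, 1 fell and 11 did not pass (7 and 1 over the list alone, median 0.87, camera adjusted p 0.145). Of 13 type 17 gamma-delta genes, 3 rose, 5 fell and 5 did not pass (3 and 5 over the list alone, median -0.45, camera adjusted p 0.419). Klrd1, which encodes the receptor chain CD94, rose (adjusted p 0.00144), and the protease gene Gzmb fell (log2 fold change -2.53 ± 0.52, adjusted p 0.00806). Il1r1 rose and Tmem176b fell among type 17 genes (2.10 ± 0.13 and -2.29 ± 0.27). Of 7 NK and innate lymphoid markers, 2 rose, 3 fell and 2 did not pass (3 and 3 over the list alone), with a positive median of 0.39 beside a camera direction of down (adjusted p 0.756), and the Fc receptor gene Fcgr3 fell (log2 fold change -2.02 ± 0.22, adjusted p 0.000938). Of 18 maturation and migration genes, 8 rose, 6 fell and 4 did not pass (9 and 6 over the list alone, median 0.38, camera adjusted p 0.622). The egress regulators Klf2 (3.81 ± 0.28) and S1pr1 (1.74 ± 0.24) were higher. Of 23 cytokine receptors and STAT feedback genes, 4 rose, 9 fell and 10 did not pass (4 and 10 over the list alone, median -0.34, camera adjusted p 0.0551), and feedback inhibitors fell: Socs2 (-2.84 ± 0.36), Cish (-2.77 ± 0.42) and Socs3 (-2.53 ± 0.15).

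Of 11 early progenitor genes, 2 rose, 7 fell and 2 did not pass (2 and 7 over the list alone, median -1.12, camera adjusted p 0.0106). Examples were Flt3 (-1.97 ± 0.11) and Kit (-1.43 ± 0.15). Of 8 myeloid and mast cell markers, 1 rose, 5 fell and 2 did not pass (1 and 5 over the list alone, median -0.95, camera adjusted p 0.0211), with Mpo (-2.77 ± 0.27) the largest fall. Both lists had an adjusted p of 0.534 with an estimated correlation. The progenitor list did not pass without DN3 replicate 1 (0.0857) or DN3 replicate 2 (0.0943), nor the myeloid list (0.188 and 0.172), and neither passed under the stricter filter (0.141 each). Of 18 survival and apoptosis genes, 8 rose, 5 fell and 5 did not pass (8 and 5 over the list alone, median 0.31, camera adjusted p 0.622). Bcl2a1d (2.39 ± 0.21) was higher and Bcl2 (-1.86 ± 0.30) lower. Of 21 interferon-stimulated genes, 4 rose, 5 fell and 12 did not pass (4 and 5 over the list alone, median 0.01, camera direction down, adjusted p 0.756). Bst2 (-1.01 ± 0.09) fell. Among 14 stress response genes 2 rose, 5 fell and 7 did not pass (2 and 5 over the list alone, median -0.10, camera adjusted p 0.132). Trib3 (-2.18 ± 0.25) was lower. Of 4 B cell markers, 1 rose, 2 fell and 1 did not pass (1 and 2 over the list alone, median -0.27, camera adjusted p 0.748). Pou2af1 rose (2.10 ± 0.29). Erythroid markers and mitochondrially encoded transcripts had fewer than 3 members tested and no list test. Gata1 of the former fell in both populations (-1.36 ± 0.16 in CD73-negative and -1.61 ± 0.16 in CD73-positive cells).

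Most stromal cell markers, genes of fibroblast-like cells such as OP9, were higher than in DN3 in both populations. Of 17 in CD73-negative cells, 13 rose, 0 fell and 4 did not pass (13 and 0 over the list alone, median 2.59, camera adjusted p 0.000874, 0.669 with an estimated correlation). In CD73-positive cells 12 rose, 0 fell and 5 did not pass (13 and 0 over the list alone, median 2.17, camera adjusted p 0.00375, 0.551 with an estimated correlation). Col1a1 measured 42 ± 2.18 FPKM in CD73-negative, 32.6 ± 0.311 FPKM in CD73-positive and 3.29 ± 2.77 FPKM in DN3 cells. It was 5.25 FPKM in DN3 replicate 1 and 1.34 FPKM in DN3 replicate 2. Col6a1, Col6a2, Cxcl12 and Hp were among 26 tested loci chosen after the data were seen. Of these named genes, Col6a1 and Cxcl12 are members of the list and Col6a2 and Hp are not. All 26 loci were higher in DN3 replicate 1 than in DN3 replicate 2 by a log2 difference of at least 1. They were also higher in CD73-negative than in CD73-positive cells by 0.1 to 0.7 in both pairs of same-numbered libraries. Changes between replicates of a CD73 population were not part of the choice. Most members of the list met these conditions and were among the 26, Col1a1, Col1a2, Sparc and Bgn included. With those 26 loci left out the list no longer passed in CD73-negative (median 0.76, adjusted p 0.392) or CD73-positive cells (median 0.56, adjusted p 0.489). That loss follows from leaving out the members and tests no explanation.

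**Figure D1:**
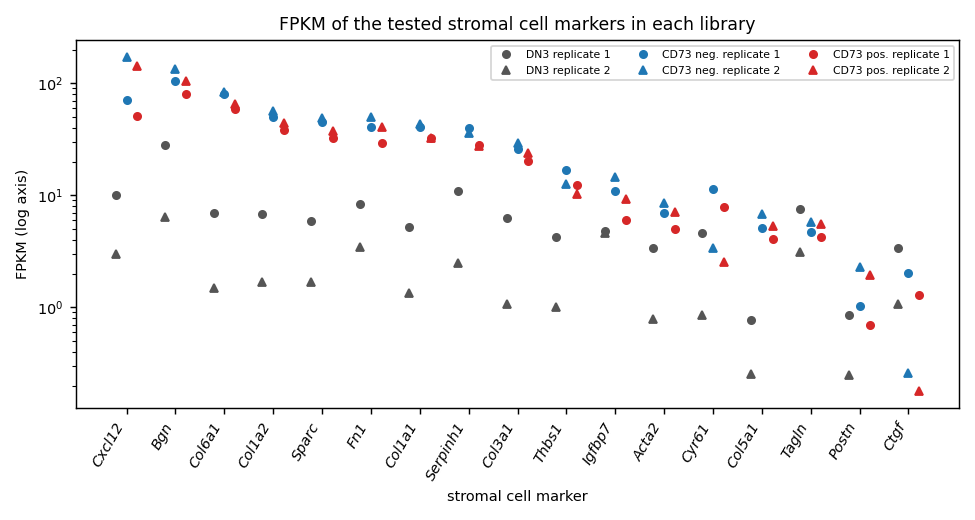
FPKM of stromal cell markers in each of the 6 libraries on a log axis, with 1 point per library. Col1a1 lies between 32.4 and 43.5 FPKM in the 4 CD73 libraries, and at 5.25 and 1.34 FPKM in the DN3 libraries.

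In CD73-positive cells the largest rises from DN3 included genes of NK-type receptors and of tissue homing. Klrd1 went from 1.26 ± 0.00786 FPKM to 179 ± 41.3 FPKM (log2 fold change 6.30 ± 0.49, adjusted p 0.000405). The locus holding its partners Klrc1, Klrc2 and Klrc3 went from 0.499 ± 0.000727 FPKM to 116 ± 17.1 FPKM (log2 fold change 6.28 ± 0.34, adjusted p 0.0002). Gpr15 and Cxcr6, receptors that direct T cells to tissues, rose by 6.17 ± 0.28 and 4.06 ± 0.19 (adjusted p 0.000164 and 0.000177). Dntt and the inhibitory receptor gene Ctla4 were among the largest falls, with Dntt at 0.432 ± 0.123 FPKM against 45.9 ± 15.8 FPKM (log2 fold change -4.99 ± 0.34, adjusted p 0.000308) and Ctla4 at 3.41 ± 0.791 FPKM against 139 ± 0.858 FPKM (log2 fold change -4.99 ± 0.13, adjusted p 5.98e-05). Other large rises were Klrk1 (4.91 ± 0.34), Klf2 (4.73 ± 0.28), Cd7 (4.61 ± 0.30), Ikzf3 (4.57 ± 0.20) and Col6a2 (3.97 ± 0.43). Col6a2 was among the 26 loci that followed the stromal markers. Other large falls were Myl10 (-7.85 ± 0.20), Vwa8 (-5.34 ± 0.15), Adgrg1 (-4.91 ± 0.29), Igf2 (-4.66 ± 0.15), Rab44 (-4.59 ± 0.19), Mpzl2 (-4.59 ± 0.31), Drc7 (-4.55 ± 0.30) and Ifi202b (-4.48 ± 0.20). The locus holding Klra5, Klra6 and Klra19 rose by 4.71 ± 1.04 with 47.5 ± 48.6 FPKM in CD73-positive cells, and did not pass without DN3 replicate 1 (adjusted p 0.0550) or DN3 replicate 2 (0.0554). Of 11434 loci, 3541 rose and 2740 fell, of which 850 and 851 changed by a log2 fold change of at least 1, and leaving out 1 library at a time gave 4431 to 5846.

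**Figure D2:**
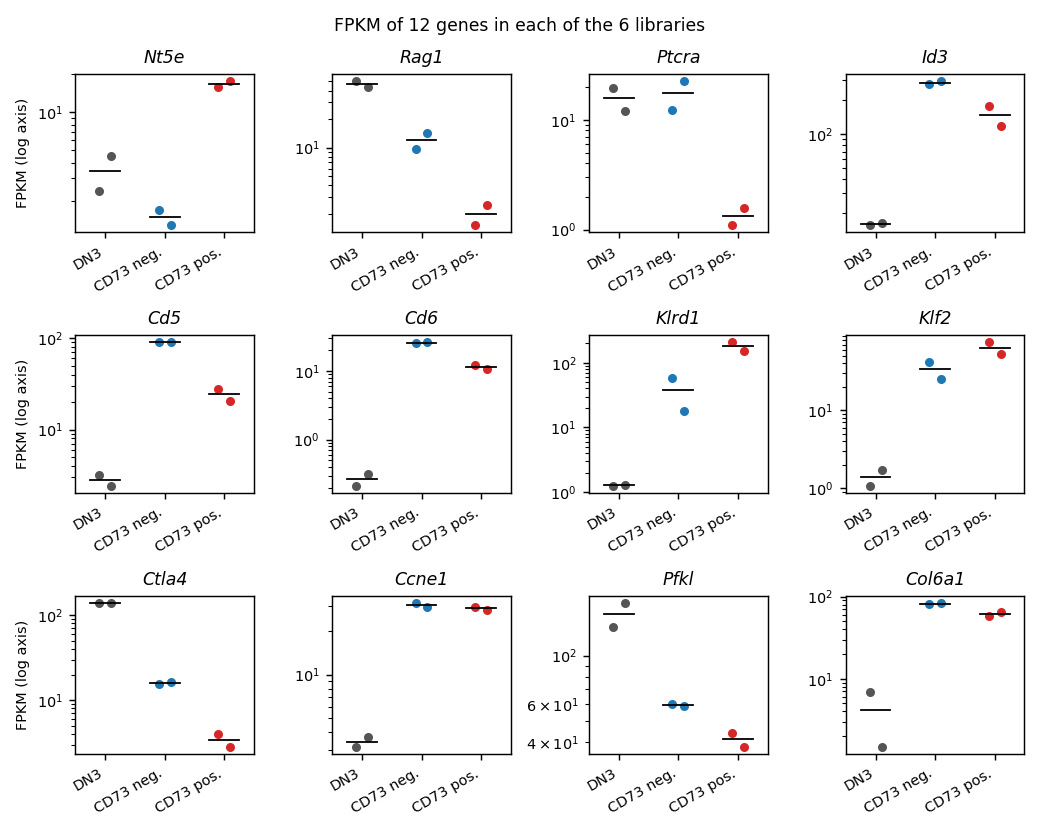
FPKM of 12 genes in each of the 6 libraries on log axes, with 1 point per library and a line at the mean of each population. Mean Cd5 was highest in CD73-negative cells at 90.4 FPKM, and mean Klrd1 in CD73-positive cells at 179 FPKM.

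The 14 DN3 stage genes fell as a list: 2 rose, 11 fell and 1 did not pass (2 and 12 over the list alone, median -2.35, camera adjusted p 0.000605, 0.551 with an estimated correlation). Alongside Rag1 and Dntt, Erg (-2.90 ± 0.33) fell, and Dtx1 rose (3.15 ± 0.19). Of 12 Notch target genes, 3 rose, 6 fell and 3 did not pass (3 and 6 over the list alone, median -1.16, camera adjusted p 0.101). Ptcra, the pre-TCR alpha chain gene (log2 fold change -2.81 ± 0.32, adjusted p 0.00111), Notch3 (-2.65 ± 0.22) and Notch1 (-2.48 ± 0.23) were lower. Of 22 T lineage transcription factors, 6 rose, 11 fell and 5 did not pass (6 and 12 over the list alone, median -0.35, camera adjusted p 0.101). Tox2 (2.62 ± 0.25) rose and Gfi1 (-2.75 ± 0.15) fell. Of 9 alpha-beta lineage genes, 3 rose, 5 fell and 1 did not pass (3 and 5 over the list alone, median -0.51, camera adjusted p 0.36). Arpp21 (-2.13 ± 0.21) was lower. Of 14 gamma-delta lineage genes, 4 rose, 3 fell and 7 did not pass (4 and 3 over the list alone, median 0.13, camera adjusted p 0.804). Il2rb (3.70 ± 0.47) was higher, and the rises include Nt5e, the gene of the sort marker. Id3 was at 148 ± 41.6 FPKM against 16.1 ± 0.39 FPKM in DN3 (adjusted p 0.000231). Cd24a, a marker of immature thymocytes, fell (-2.09 ± 0.20).

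Type 1 and cytotoxic genes rose as a list. Of the 19, 12 rose, 0 fell and 7 did not pass (12 and 0 over the list alone, median 1.31, camera adjusted p 0.00385, 0.551 with an estimated correlation). The largest rises were Klrd1, the Klrc locus and Klrk1 (4.91 ± 0.34). Of 7 NK and innate lymphoid markers, 5 rose, 0 fell and 2 did not pass (5 and 0 over the list alone), and the list did not pass (median 0.88, camera adjusted p 0.0688). Ncr1, a receptor of NK cells and innate lymphoid cells, rose from 0.204 ± 0.0103 FPKM to 13.3 ± 5.79 FPKM (log2 fold change 3.51 ± 0.29, adjusted p 0.000445). Of 13 type 17 gamma-delta genes, 3 rose, 4 fell and 6 did not pass (3 and 4 over the list alone, median -0.18, camera adjusted p 0.443). Tmem176b (-2.72 ± 0.27) was lower. Of 18 maturation and migration genes, 11 rose, 4 fell and 3 did not pass (11 and 4 over the list alone, median 0.89, camera adjusted p 0.0932). Klf2 and S1pr1 (3.14 ± 0.24) rose, and Cxcr4 (-2.51 ± 0.16) fell. Of 17 costimulatory and inhibitory receptors, 9 rose, 2 fell and 6 did not pass (9 and 2 over the list alone, median 0.75, camera adjusted p 0.123). Pdcd1 (2.92 ± 0.25) and Cd40lg (2.89 ± 0.25) were higher and Havcr2 (-4.24 ± 0.29) lower. Of 23 cytokine receptors and STAT feedback genes, 6 rose, 11 fell and 6 did not pass (7 and 11 over the list alone, median -0.53, camera adjusted p 0.101). Il2rb, the shared IL-2 and IL-15 receptor chain, rose, and Socs2 (-3.18 ± 0.36), Il10ra (-3.16 ± 0.19) and Cish (-3.10 ± 0.42) fell.

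TCR signal-induced genes rose from DN3 here too. Of the 23, 17 rose, 1 fell and 5 did not pass (17 and 1 over the list alone, median 1.21, camera adjusted p 0.000266, 0.551 with an estimated correlation). Examples were Cd6 (3.31 ± 0.11) and Egr3 (2.89 ± 0.41). Of 23 TCR signalling components, 6 rose, 11 fell and 6 did not pass (7 and 11 over the list alone, median -0.42, camera adjusted p 0.165). Syk (-2.26 ± 0.24) and Plcg1 (-1.38 ± 0.09) were lower and Ptpn22 (1.37 ± 0.23) higher. S phase genes rose throughout. Of the 24, 24 rose, 0 fell and 0 did not pass (24 and 0 over the list alone, median 0.84, camera adjusted p 4.47e-08). So did G2/M genes. Of the 22, 22 rose, 0 fell and 0 did not pass (22 and 0 over the list alone, median 0.97, camera adjusted p 1.28e-08). Examples were Ccne1 (2.76 ± 0.09), Rrm2 (1.91 ± 0.14), Birc5 (1.54 ± 0.08) and Mki67 (1.33 ± 0.14). Of 22 ribosome biogenesis genes, 17 rose, 1 fell and 4 did not pass (19 and 1 over the list alone, median 0.56, camera adjusted p 0.00115). Ddx21 (1.00 ± 0.17) was higher and Wdr12 (-1.06 ± 0.13) lower. Of 25 oxidative phosphorylation genes, 21 rose, 0 fell and 4 did not pass (23 and 0 over the list alone, median 0.48, camera adjusted p 3.06e-06), with Ndufa4 (1.30 ± 0.09) highest. Glycolysis genes fell. Of the 18, 1 rose, 16 fell and 1 did not pass (1 and 16 over the list alone, median -1.20, camera adjusted p 4.67e-05). Examples were Slc2a3 (-2.45 ± 0.35) and Pfkl (-1.88 ± 0.13). Each of these 5 lists had an adjusted p of 0.551 with an estimated correlation. Cholesterol synthesis genes did not pass. Of the 23, 8 rose, 1 fell and 14 did not pass (7 and 1 over the list alone, median 0.20, camera adjusted p 0.101). Pmvk (0.97 ± 0.14) rose.

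Early progenitor genes fell. Of the 11, 1 rose, 8 fell and 2 did not pass (3 and 8 over the list alone, median -1.23, camera adjusted p 0.0124). Examples were Nfe2 (-3.11 ± 0.20), Bcl11a (-2.70 ± 0.19) and Lyl1 (-2.42 ± 0.32). Stress response genes fell. Of the 14, 1 rose, 8 fell and 5 did not pass (2 and 8 over the list alone, median -0.54, camera adjusted p 0.0266). Examples were Trib3 (-2.49 ± 0.25) and Ddit3 (-1.33 ± 0.10). Both lists had an adjusted p of 0.551 with an estimated correlation. The progenitor list did not pass without DN3 replicate 1 (0.106), without DN3 replicate 2 (0.113) or under the stricter filter (0.266), and the stress list did not pass without DN3 replicate 2 (0.0766). Of 8 myeloid and mast cell markers, 3 rose, 4 fell and 1 did not pass (3 and 4 over the list alone, median -0.56, camera adjusted p 0.368). Mpo was 0.0427 ± 0.00819 FPKM against 10.6 ± 4.15 FPKM (log2 fold change -3.43 ± 0.27, adjusted p 0.000413). Of 18 survival and apoptosis genes, 8 rose, 4 fell and 6 did not pass (8 and 4 over the list alone, median 0.21, camera adjusted p 0.36). Bcl2 (-2.40 ± 0.30) was lower. Of 21 interferon-stimulated genes, 8 rose, 4 fell and 9 did not pass (8 and 4 over the list alone, median 0.16, camera adjusted p 0.642). Bst2 (-1.13 ± 0.09) was lower and Ifit3 (0.87 ± 0.14) higher. Of 4 B cell markers, 1 rose, 2 fell and 1 did not pass (2 and 2 over the list alone, median -0.12, camera adjusted p 0.878), with Pou2af1 higher (2.15 ± 0.29).

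Between CD73-positive and CD73-negative cells the largest rises included innate-type receptor genes, and the largest falls included a gene of receptor assembly. Klrk1, which encodes the activating receptor NKG2D, went from 2.1 ± 1.62 FPKM to 31.6 ± 0.659 FPKM (log2 fold change 3.50 ± 0.34, adjusted p 0.00788). Ncr1 went from 0.596 ± 0.294 FPKM to 13.3 ± 5.79 FPKM (log2 fold change 3.12 ± 0.29, adjusted p 0.00788). The locus holding Nfkbid and Tyrobp, a signalling adaptor of NK receptors, rose from 27 ± 4.25 FPKM to 260 ± 37.6 FPKM (log2 fold change 3.22 ± 0.16, adjusted p 0.00343), though the value cannot be assigned to either gene. Ptcra, needed for the pre-TCR of the alpha-beta route, fell from 17.4 ± 7.1 FPKM to 1.34 ± 0.324 FPKM (log2 fold change -2.93 ± 0.32, adjusted p 0.00886). Gzmb, the largest rise, went from 14.9 ± 4.51 FPKM to 229 ± 37 FPKM (log2 fold change 3.88 ± 0.52, adjusted p 0.0125) but did not pass without CD73-negative replicate 2 (adjusted p 0.086) or CD73-positive replicate 2 (0.0688). Further large rises that passed without any single library were Ifitm1 (3.60 ± 0.27), Fam179a (3.53 ± 0.30), Fcgr3 (3.22 ± 0.22) and the Klrc locus (3.26 ± 0.34), and such falls were Ifi202b (-2.58 ± 0.20) and Mzb1 (-2.48 ± 0.26). Adgrg1 fell likewise, at 3.12 ± 0.201 FPKM against 36.2 ± 17.1 FPKM (adjusted p 0.00788). Of 11434 loci 826 rose and 824 fell, of which 264 and 135 changed by a log2 fold change of at least 1. Those 1650 loci became 615 and 115 without CD73-negative replicates 1 and 2, 545 and 134 without CD73-positive replicates 1 and 2, and 2376 and 2364 without DN3 replicates 1 and 2. Without the filter they were 929, and 0 against a minimum log2 fold change of 1 (limma's treat, 205 at unadjusted p under 0.05).

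**Figure D3:**
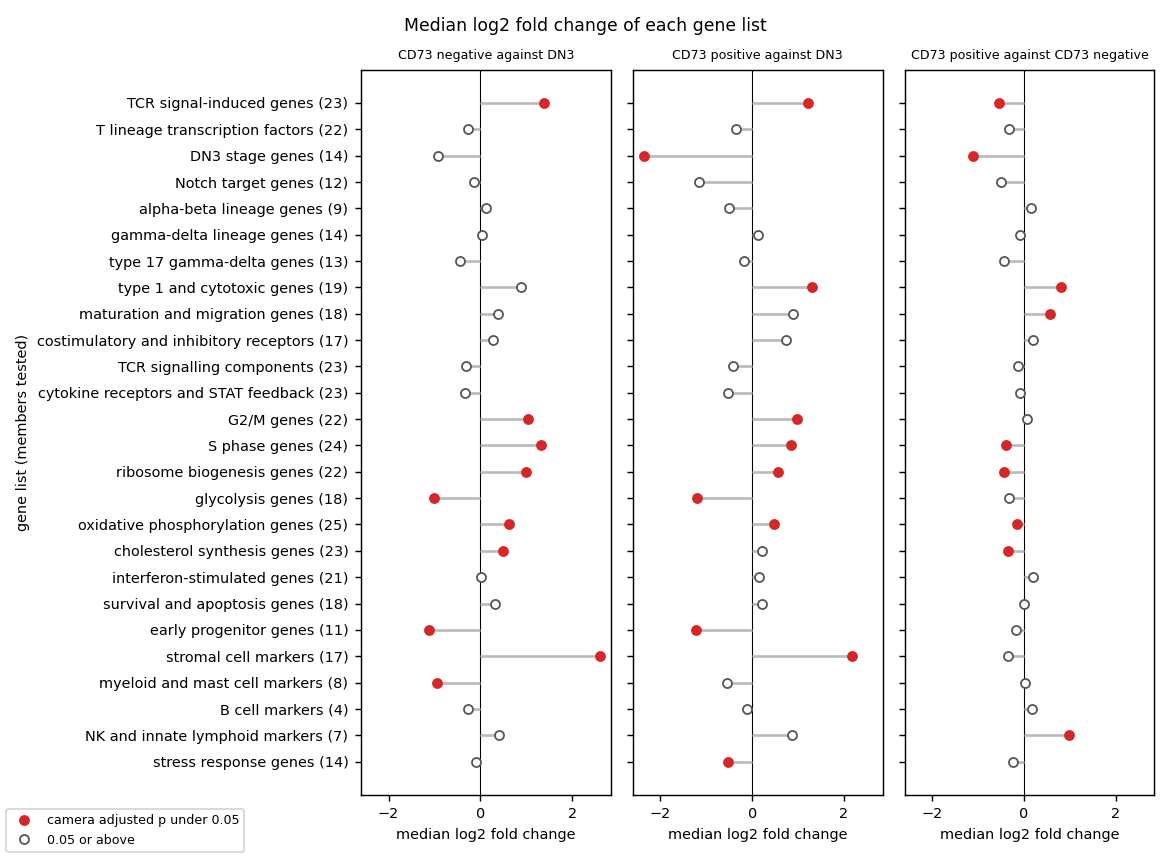
Median log2 fold change of the 26 tested gene lists on the horizontal axis, with 1 panel per comparison and filled points where the camera adjusted p was under 0.05. S phase genes had medians of 1.31 and 0.84 against DN3 and -0.39 between the CD73 populations.

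Id2, an E protein inhibitor of innate-like lymphocytes, went from 73.5 ± 9.65 FPKM to 417 ± 116 FPKM (log2 fold change 2.47 ± 0.21, adjusted p 0.00678). Zbtb7b, which encodes ThPOK, went from 2.39 ± 0.17 FPKM to 13.6 ± 2.56 FPKM (log2 fold change 2.09 ± 0.20, adjusted p 0.00788). Of 22 T lineage transcription factors, 2 rose, 7 fell and 13 did not pass (5 and 9 over the list alone, median -0.34, camera adjusted p 0.273), with Gfi1 lower (-1.71 ± 0.15). DN3 stage genes fell as a list. Of the 14, 1 rose, 8 fell and 5 did not pass (1 and 9 over the list alone, median -1.11, camera adjusted p 0.00169, 0.725 with an estimated correlation). Examples were Ptcra, Rag1 and Notch3 (-1.81 ± 0.22). Of 12 Notch target genes, 1 rose, 5 fell and 6 did not pass (1 and 6 over the list alone, median -0.50, camera adjusted p 0.104). Of 9 alpha-beta lineage genes, 0 rose, 3 fell and 6 did not pass (3 and 3 over the list alone), with a positive median of 0.15 beside a camera direction of down (adjusted p 0.853). Ptcra, also a member of the DN3 stage and Notch target lists, was the largest fall. Of 14 gamma-delta lineage genes, 3 rose, 4 fell and 7 did not pass (5 and 6 over the list alone), with a negative median of -0.08 beside a camera direction of up (adjusted p 0.922). The rise of Nt5e, the gene of the sort marker, was set in advance by the sort. Blk fell (log2 fold change -2.03 ± 0.31, adjusted p 0.0163). Blk did not pass without CD73-negative replicate 2 (adjusted p 0.0846), CD73-positive replicate 1 (0.0557) or CD73-positive replicate 2 (0.0563). Of 13 type 17 gamma-delta genes, 4 rose, 3 fell and 6 did not pass (5 and 5 over the list alone, median -0.43, camera adjusted p 0.948), and of these Etv5 fell (-1.49 ± 0.20) but did not pass without CD73-negative replicate 2 (0.055) or CD73-positive replicate 2 (0.0627).

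The list of NK and innate lymphoid markers passed upward between the CD73 populations. Of 14 members named, 7 were tested, and of the 7, 3 rose, 0 fell and 4 did not pass (5 and 0 over the list alone, median 0.97, camera adjusted p 0.00169). Among the rises, Gzmc did not pass when any 1 of the 4 CD73 libraries was left out (log2 fold changes 2.08 to 2.95). The list of type 1 and cytotoxic genes passed, too. Of the 19, 8 rose, 0 fell and 11 did not pass (8 and 1 over the list alone, median 0.81, camera adjusted p 0.00169). Both had an adjusted p of 0.725 with an estimated correlation, and the type 1 list did not pass without CD73-positive replicate 1 (0.192). The list of maturation and migration genes passed, also upward. Of the 18, 6 rose, 2 fell and 10 did not pass (9 and 2 over the list alone, median 0.58, camera adjusted p 0.00547, 0.725 with an estimated correlation). An example was Itgae, an integrin chain of tissue-resident lymphocytes (40.3 ± 10.4 FPKM to 158 ± 36.2 FPKM, log2 fold change 1.95 ± 0.21, adjusted p 0.00886). Of 17 costimulatory and inhibitory receptors, 4 rose, 1 fell and 12 did not pass (4 and 2 over the list alone, median 0.21, camera adjusted p 0.264). Ctla4 (-1.96 ± 0.13) fell, and Icos rose (2.55 ± 0.29), though not past the threshold without CD73-negative replicate 2 (adjusted p 0.0603). Of 23 cytokine receptors and STAT feedback genes, 6 rose, 4 fell and 13 did not pass (7 and 5 over the list alone), with a median of -0.08 beside a camera direction of up (adjusted p 0.497). Il18r1 rose (log2 fold change 2.73 ± 0.32, adjusted p 0.00964) but did not pass without CD73-negative replicate 2 (0.053) or CD73-positive replicate 2 (0.0551). The list of TCR signal-induced genes, most of which had risen from DN3 in both populations, passed downward. Of the 23, 1 rose, 8 fell and 14 did not pass (2 and 9 over the list alone, median -0.55, camera adjusted p 0.00383, 0.725 with an estimated correlation). Cd5 went from 90.4 ± 0.234 FPKM to 24.3 ± 4.98 FPKM (log2 fold change -1.87 ± 0.16, adjusted p 0.00678), and the feedback inhibitor Spry1 fell (-1.30 ± 0.10). Of 23 TCR signalling components, 2 rose, 2 fell and 19 did not pass (2 and 2 over the list alone, median -0.13, camera adjusted p 0.714).

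The list of S phase genes passed downward from CD73-negative to CD73-positive cells. Of the 24, 0 rose, 7 fell and 17 did not pass (0 and 17 over the list alone, median -0.39, camera adjusted p 1.96e-06), with Gins1, part of the replicative helicase, at 23.6 ± 1.54 FPKM against 37 ± 2.45 FPKM (log2 fold change -0.63 ± 0.09, adjusted p 0.0136). The list of ribosome biogenesis genes passed downward. Of the 22, 0 rose, 10 fell and 12 did not pass (0 and 17 over the list alone, median -0.43, camera adjusted p 6.72e-07). The list of cholesterol synthesis genes passed downward. Of the 23, 0 rose, 6 fell and 17 did not pass (0 and 12 over the list alone, median -0.35, camera adjusted p 0.00169). Of 25 oxidative phosphorylation genes, 1 rose, 2 fell and 22 did not pass (1 and 5 over the list alone, median -0.14, camera adjusted p 0.00375), and this list alone of the 9 past the threshold did not pass under quantile normalization (adjusted p 0.0618). These 4 lists had an adjusted p of 0.725 with an estimated correlation. Gins1 did not pass without CD73-negative replicate 2 (adjusted p 0.114) or CD73-positive replicate 2 (0.0867). The example of ribosome biogenesis, Nop56 (-0.64 ± 0.10), did not pass without CD73-negative replicate 1 (0.0579), CD73-negative replicate 2 (0.116) or CD73-positive replicate 2 (0.0789). Of 22 G2/M genes, 1 rose, 1 fell and 20 did not pass (1 and 1 over the list alone, median 0.06, camera adjusted p 0.489). Of 18 glycolysis genes, 0 rose, 0 fell and 18 did not pass (0 and 0 over the list alone, median -0.33, camera adjusted p 0.0805), with Pfkl at -0.52 ± 0.13 (adjusted p 0.0531). Of 11 early progenitor genes, 2 rose, 3 fell and 6 did not pass (2 and 4 over the list alone, median -0.18, camera adjusted p 0.438). Kit, the stem cell factor receptor, rose from 30.1 ± 0.954 FPKM to 110 ± 15.9 FPKM (log2 fold change 1.83 ± 0.15, adjusted p 0.00678). Of 8 myeloid and mast cell markers, 2 rose, 1 fell and 5 did not pass (2 and 1 over the list alone, median 0.01, camera adjusted p 0.424). Of 4 B cell markers, 0 rose, 0 fell and 4 did not pass (0 and 0 over the list alone, median 0.18, camera adjusted p 0.555). Of 17 stromal cell markers, 0 rose, 0 fell and 17 did not pass (0 and 0 over the list alone, median -0.35, camera adjusted p 0.34). All 17 were lower in CD73-positive cells in both pairs of same-numbered libraries, and the list passed in a fit on the 4 CD73 libraries (adjusted p 0.0114) and without DN3 replicate 1 (0.0117) or 2 (0.0113). Of 21 interferon-stimulated genes, 2 rose, 0 fell and 19 did not pass (0 and 0 over the list alone, median 0.19, camera adjusted p 0.224). Of 14 stress response genes, 1 rose, 0 fell and 13 did not pass (0 and 0 over the list alone, median -0.25, camera adjusted p 0.34). Of 18 survival and apoptosis genes, 1 rose, 0 fell and 17 did not pass (1 and 0 over the list alone, median -0.01, camera direction up, adjusted p 0.714).

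Most loci that changed from DN3 changed in both populations: 2753 were higher and 2132 lower in both, against 1128 and 678 if the calls were independent. They included Cd6, Id3 and Ikzf3 among the rises and Myl10, Igf2 and Vwa8 among the falls, and 16 and 33 loci were called in opposite directions. Across loci, which are not independent replicates, the log2 fold changes had a correlation of 0.842 and a covariance of 0.532. Both comparisons use the same DN3 libraries, and data simulated with no difference gave a correlation of 0.499, a covariance of 0.0153, and 0.02 loci higher and 0.01 lower in both. With 2 DN3 libraries, each comparison cannot have 2 of its own, so part of the excess in shared calls may come from the shared controls. The covariance exceeded the simulated value by 0.516. The simulation held only the spread between replicates, so anything common to both DN3 libraries stays in that excess. Of the loci higher in CD73-negative cells than in DN3, 472 were lower in CD73-positive than in CD73-negative cells (262 if independent) and 165 higher (263). Cd5 was one of the 472. Of those lower than in DN3, 290 were higher in CD73-positive than in CD73-negative cells (204 if independent) and 177 lower (204). Ifitm1 was among the former and Dntt among the latter. Between the CD73 populations Dntt did not pass without CD73-positive replicate 2, where its log2 fold change was -2.85. These comparisons share the CD73-negative libraries, for which simulation gave a correlation of -0.487 and a covariance of -0.0148, against -0.134 and -0.0462 measured. Noise in those libraries enters the comparisons with opposite sign, so part of the excess in the 472 and 290 may come from it. The CD73 populations were sorted after the same 3 days, so these counts show no order in time.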

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

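Loci without a gene name were left out of the comparisons, and some lie over antigen receptor genes of the reference annotation. Their values, obtained with unnamed loci included in the fit, were examined after the data were seen and are given where a CD73 population was above the level in DN3 cells and had a mean of at least 5 FPKM. They are log2 fold changes with SE, past an adjusted p of 0.05, at mm10 positions.

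Over T cell receptor genes, a locus at chr14:54151086-54223919, over Trac and Traj segments, measured 31.0 FPKM in CD73-negative, 15.3 in CD73-positive and 1.65 in DN3 cells (3.55 ± 0.47 and 2.51 ± 0.47 against DN3). A locus at chr14:54224040-54224210, over Trac, measured 14.9 and 17.9 FPKM and was listed at 0 in both DN3 libraries (fitted values 3.99 ± 0.58 and 3.93 ± 0.58, no fold being defined). A locus at chr14:54045937-54089764, over the delta chain segment Trdv4, measured 9.35, 17.4 and 3.19 FPKM (1.28 ± 0.25 and 2.15 ± 0.25). At chr13:19334522-19353664, over Tcrg-C4 and Tcrg-V1, a pair of loci with the same coordinates was higher in CD73-positive cells than in DN3 (0.50 ± 0.11 and 0.29 ± 0.10).

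Over immunoglobulin heavy chain genes, a locus at chr12:113418556-113430669, over Ighd and Ighj segments, was higher than in DN3 in CD73-negative (1.35 ± 0.23) and CD73-positive cells (1.67 ± 0.23). A locus at chr12:115476547-115659414, over Ighv segments, was higher in CD73-positive cells (2.12 ± 0.30). Most other receptor loci were lower than in DN3 past the threshold in both populations. They included loci over Tcrg-C2 (-1.99 ± 0.09 and -2.09 ± 0.09) and over Trbc1 and Trbc2 (-0.71 ± 0.08 and -0.58 ± 0.08). The locus over Tcrg-C1 and Tcrg-C3 (-1.79 ± 0.21 and -1.39 ± 0.21) was lower too. So was that over Trbv14 to Trbv16 at chr6:41134811-41153328 with the highest FPKM (-3.42 ± 0.12 and -4.25 ± 0.12). Immunoglobulin loci went both ways, as that over Ighv1-85 went from 193 FPKM in DN3 to 3.98 and 0 FPKM. No explanation of these values was tested.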

How the results depend on the processing

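The alternatives that include loci without a gene name, leave out loci with several names or leave out 26 loci following the stromal markers were chosen after seeing the data, and the others before the data were examined. Over 18 alternatives that refit every locus, 0 of 318 named gene results (limma, 311 past the threshold) and 0 called lists changed direction. Most named genes were chosen as past the threshold in these same data, those of largest change also with non-overlapping libraries. A change of direction was therefore unlikely beforehand, and its absence says little about stability. With the other list tests included, 37 list results turned, all outside the threshold in both settings. Changed loci ranged from 5218 to 7002 for CD73-negative and from 4970 to 6911 for CD73-positive cells against DN3 under other pseudocounts, filters, scalings and fits. Between the CD73 populations they ranged from 929, without a filter, to 2293, in a fit on 4 libraries. Leaving out 1 library at a time gave 4326 to 5900, 4431 to 5846 and 115 to 2376. A library left alone in its population is then assumed to vary like the others, and fewer libraries leave fewer degrees of freedom. Limma's treat against a log2 fold change of 1 gave 263, 504 and 0 loci, and 865, 1018 and 205 at unadjusted p under 0.05, a stricter test by its construction. Higher loci made up 56.3%, 56.4% and 50.1% of calls as reported, 50.4%, 51.3% and 52.1% after median-ratio rescaling, and 52.2%, 52.0% and 53.0% after quantile normalization. Between the CD73 populations the share ran from 44.3% in a fit on 4 libraries to 56.1% without a filter, with 46.1% under the stricter filter. Loci changed in the same direction in both CD73 populations numbered 4885, and 3399 to 4465 with 1 library left out.

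Of 86 named genes past the threshold between the CD73 populations, 59 kept their call without CD73-negative replicate 1 and 34 without CD73-negative replicate 2. Of the 84 testable without a CD73-positive library, 50 kept it without replicate 1 and 31 without replicate 2, and of 86, 81 and 80 without DN3 replicates 1 and 2. Against DN3 between 100 and 113 named genes kept their call whichever library was left out. Without the filter 106 of 112, 110 of 113 and 58 of 86 kept it. The labels do not say whether the replicate numbers pair the libraries, and the main fit did not use them. With the number as a block in all 3 populations 6646, 6476 and 1739 loci passed. Replicate differences correlated across loci at 0.378 between CD73-negative and CD73-positive, 0.118 between CD73-negative and DN3 and 0.0147 between CD73-positive and DN3 libraries. The value of 0.378 leaves a pairing of the CD73 libraries possible, and a block over them alone was not run.

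Each list median is followed by the adjusted p of its test. With a correlation estimated for each list, camera called 0, 0 and 0 lists. This changes the test and not the medians. The lists that lost their call in CD73-negative cells, with their medians, were TCR signal-induced (1.37), G2/M (1.04), S phase (1.31), ribosome biogenesis (0.98), glycolysis (-1.01), oxidative phosphorylation (0.62), cholesterol synthesis (0.48), early progenitor (-1.12), stromal cell (2.59) and myeloid (-0.95). The lists that lost their call in CD73-positive cells, with their medians, were TCR signal-induced (1.21), DN3 stage (-2.35), type 1 (1.31), G2/M (0.97), S phase (0.84), ribosome biogenesis (0.56), glycolysis (-1.20), oxidative phosphorylation (0.48), early progenitor (-1.23), stromal cell (2.17) and stress response (-0.54). The lists that lost their call between the CD73 populations, with their medians, were TCR signal-induced (-0.55), DN3 stage (-1.11), type 1 (0.81), maturation (0.58), S phase (-0.39), ribosome biogenesis (-0.43), oxidative phosphorylation (-0.14), cholesterol synthesis (-0.35) and NK (0.97). Fry called 13, 21 and 0 lists (14, 21 and 13 at unadjusted p under 0.05), and tests a list without comparing it with other genes. Lists called by camera and not by fry in CD73-negative cells were glycolysis (-1.01, p 0.072). Lists called by camera and not by fry between the CD73 populations were TCR signal-induced (-0.55, p 0.0987), DN3 stage (-1.11, p 0.0932), type 1 (0.81, p 0.269), maturation (0.58, p 0.0932), S phase (-0.39, p 0.0932), ribosome biogenesis (-0.43, p 0.0932), oxidative phosphorylation (-0.14, p 0.0932), cholesterol synthesis (-0.35, p 0.0987) and NK (0.97, p 0.0932). Lists called by fry alone in CD73-negative cells were costimulatory receptors (0.27, p 0.0266), cytokine and STAT (-0.34, p 0.00584), survival (0.31, p 0.0201) and stress response (-0.0987, p 0.0173). Lists called by fry alone in CD73-positive cells were T lineage factors (-0.35, p 0.0268), Notch target (-1.16, p 0.0153), alpha-beta lineage (-0.51, p 0.0293), maturation (0.89, p 0.0153), costimulatory receptors (0.75, p 0.0268), TCR signalling (-0.42, p 0.0433), cytokine and STAT (-0.53, p 0.00387), survival (0.21, p 0.0162), myeloid (-0.56, p 0.0153) and NK (0.88, p 0.0268). Outside both thresholds fry had the opposite direction for gamma-delta lineage (0.032, p 0.137), type 17 (-0.45, p 0.976) and interferon-stimulated (0.00658, p 0.938) in CD73-negative cells, and B cell (-0.12, p 0.971) in CD73-positive cells, and gamma-delta lineage (-0.079, p 0.955) between the CD73 populations.

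Without a filter calls were gained for type 1 (0.76, p 0.0477), cytokine and STAT (-0.34, p 0.0477) and stress response (-0.15, p 0.0445) in CD73-negative cells, and maturation (0.63, p 0.0436), cholesterol synthesis (0.20, p 0.0436), myeloid (-0.22, p 0.0169) and NK (0.65, p 0.0169) in CD73-positive cells. Without a filter the camera direction turned, outside the threshold, for alpha-beta lineage (0.13, p 0.949) and gamma-delta lineage (0.032, p 0.976) in CD73-negative cells, and type 17 (0.0189, p 0.724) and B cell (-0.0513, p 0.724) between the CD73 populations. With at least 5 FPKM in 2 libraries calls were lost for early progenitor (-1.43, p 0.141) and myeloid (-0.59, p 0.141) in CD73-negative cells, and early progenitor (-2.42, p 0.266) in CD73-positive cells. With at least 5 FPKM in 2 libraries calls were gained for cytokine and STAT (-0.39, p 0.022) in CD73-negative cells, and cytokine and STAT (-0.61, p 0.0421) in CD73-positive cells, and interferon-stimulated (0.24, p 0.0483) between the CD73 populations. With at least 5 FPKM in 2 libraries the camera direction turned, outside the threshold, for costimulatory receptors (0.26, p 0.96) in CD73-negative cells, and myeloid (0.19, p 0.98) and B cell (0.39, p 0.713) in CD73-positive cells. After median-ratio rescaling calls were gained for NK (0.86, p 0.0487) in CD73-positive cells. After median-ratio rescaling the camera direction turned, outside the threshold, for gamma-delta lineage (-0.0286, p 0.933) in CD73-negative cells. After quantile normalization calls were lost for oxidative phosphorylation (-0.097, p 0.0618) between the CD73 populations. After quantile normalization calls were gained for DN3 stage (-0.94, p 0.0468) and cytokine and STAT (-0.46, p 0.0468) in CD73-negative cells. In fits on 4 libraries calls were gained for DN3 stage (-0.92, p 0.0472) in CD73-negative cells, and maturation (0.89, p 0.0337) and NK (0.88, p 0.0339) in CD73-positive cells, and glycolysis (-0.33, p 0.0472) and stromal cell (-0.35, p 0.0114) between the CD73 populations. In fits on 4 libraries the camera direction turned, outside the threshold, for alpha-beta lineage (0.15, p 0.982) between the CD73 populations. With the replicate number as a block calls were gained for DN3 stage (-0.92, p 0.041) and cytokine and STAT (-0.34, p 0.0446) in CD73-negative cells, and NK (0.88, p 0.0442) in CD73-positive cells. With the replicate number as a block the camera direction turned, outside the threshold, for B cell (-0.12, p 0.901) in CD73-positive cells. With unnamed loci included the camera direction turned, outside the threshold, for gamma-delta lineage (0.032, p 0.97) in CD73-negative cells. Without loci of several names calls were gained for myeloid (-1.41, p 0.022) in CD73-positive cells. Without loci of several names the camera direction turned, outside the threshold, for type 17 (-0.11, p 0.86) and myeloid (-0.25, p 0.86) between the CD73 populations. Without the loci following the stromal markers calls were lost for stromal cell (0.76, p 0.392) in CD73-negative cells, and stromal cell (0.56, p 0.489) in CD73-positive cells. With a pseudocount of 0.1 the camera direction turned, outside the threshold, for type 17 (-0.46, p 0.908) between the CD73 populations. The loss of the stromal list follows from leaving out its members, and the cause of the other changes was not tested. Pseudocount 5 and eBayes without the trend changed 0 list calls with camera.

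Leaving out 1 library at a time, the medians of lists that lost or gained a call or turned in camera direction had these ranges. They were DN3 stage -1.11 to -0.61, gamma-delta lineage -0.33 to 0.0792, type 1 0.35 to 1.21 and cytokine and STAT -0.39 to -0.27 in CD73-negative cells. Also in CD73-negative cells they were interferon-stimulated -0.27 to 0.25, early progenitor -1.33 to -0.78, myeloid -1.06 to -0.55 and B cell -0.41 to 0.22. They were maturation 0.82 to 1.11, costimulatory receptors 0.44 to 0.98, cytokine and STAT -0.56 to -0.49, cholesterol synthesis 0.10 to 0.30 and interferon-stimulated -0.0987 to 0.45 in CD73-positive cells. Also in CD73-positive cells they were early progenitor -1.66 to -0.64, myeloid -0.67 to 0.22, B cell -0.13 to 0.53, NK 0.61 to 1.26 and stress response -0.56 to -0.48. They were Notch target -0.69 to -0.47, alpha-beta lineage -0.12 to 0.21, gamma-delta lineage -0.25 to 0.0892, type 17 -0.58 to -0.0661 and type 1 0.24 to 1.66 between the CD73 populations. Also between the CD73 populations they were glycolysis -0.44 to -0.20, survival -0.0289 to 0.11, stromal cell -0.47 to -0.27 and B cell -0.037 to 0.37. Calls gained in CD73-negative cells, with adjusted p, were DN3 stage (0.00449) and type 1 (0.00338) without CD73-negative replicate 2, DN3 stage (0.0456) and cytokine and STAT (0.0312) without CD73-positive replicate 1 and DN3 stage (0.046) and cytokine and STAT (0.0313) without CD73-positive replicate 2. Further gains in CD73-negative cells were cytokine and STAT (0.0254) without CD73-negative replicate 1 and cytokine and STAT (0.04) without DN3 replicate 1. Calls gained in CD73-positive cells, with adjusted p, were maturation (0.033) and NK (0.0493) without CD73-negative replicate 1 and maturation (0.033) and NK (0.0341) without CD73-negative replicate 2. Further gains in CD73-positive cells were maturation (0.0441), costimulatory receptors (0.0406), cholesterol synthesis (0.0121) and NK (0.0406) without CD73-positive replicate 2 and cytokine and STAT (0.0315) without CD73-positive replicate 1. Calls gained between the CD73 populations, with adjusted p, were Notch target (0.0208) without CD73-negative replicate 1, Notch target (0.0391) without CD73-positive replicate 2 and glycolysis (0.00872) without CD73-negative replicate 2. Further gains between the CD73 populations were glycolysis (0.016) without CD73-positive replicate 1, glycolysis (0.0432) and stromal cell (0.0117) without DN3 replicate 1 and glycolysis (0.044) and stromal cell (0.0113) without DN3 replicate 2. Calls were lost for early progenitor lists (p 0.0857 and 0.0943 in CD73-negative, 0.106 and 0.113 in CD73-positive cells) and the myeloid list in CD73-negative cells (0.188 and 0.172) without DN3 replicates 1 and 2. They were also lost for the stress response list without DN3 replicate 2 (0.0766) and the type 1 list between the CD73 populations without CD73-positive replicate 1 (0.192), and the cause was not tested. Relative depth ran from 0.853 to 1.26 of that in CD73-negative library 1. With 2 libraries per population, simulated changes of 1.5-fold were recovered in 52.2% to 61.2% of genes, so changes of that size can be missed.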

Other observations

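The hypoxia response, imprinted and Gimap lists, and the tests of explanations with their mature NK and CD3 genes, were chosen after the result was seen, while the stromal, NK and type 1 lists were fixed before. Hypoxia response genes fell from DN3 in both CD73 populations: 20 of 23 in CD73-negative cells (median -1.35, camera adjusted p 2.08e-08) and 21 of 23 in CD73-positive cells (median -1.45, camera adjusted p 1.14e-09), with adjusted p 0.181 and 0.300 with an estimated correlation. They included Vegfa (-2.70 ± 0.16), Bnip3 (-2.50 ± 0.23) and Egln3 (-1.70 ± 0.18) in CD73-negative cells. Between the CD73 populations 1 fell (median -0.23, adjusted p 0.0632). Of 14 imprinted genes, 7 fell and 2 rose in CD73-negative cells (median -0.49, adjusted p 0.0205, 0.181 with an estimated correlation), and 7 fell and 5 rose in CD73-positive cells (median -0.49, adjusted p 0.132). From CD73-negative to CD73-positive cells 3 rose (median 0.18, adjusted p 0.0162, 0.227 with an estimated correlation). The 7 Gimap genes, of mature lymphocyte survival, did not pass as a list (adjusted p 0.854, 0.880 and 0.949), with 1 higher and 1 lower in CD73-negative and 1 lower in CD73-positive cells.

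Transcription factors of type 1 cells varied between libraries of a population. Eomes measured 11.5 and 1.27 FPKM in CD73-negative libraries 1 and 2, and 18.1 and 2.90 FPKM in CD73-positive libraries 1 and 2. Tbx21 measured 1.93 and 0.461 FPKM in the former and 9.40 and 4.03 FPKM in the latter.

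Of 17 stromal cell markers, 13 were higher in CD73-negative and 12 in CD73-positive cells than in DN3, the most abundant being Cxcl12 (121 FPKM in CD73-negative cells), Bgn (120) and Col6a1 (81.9), and 12 were at 1 FPKM or more in both DN3 libraries. RNA carried over from the stromal layer is a candidate, and no sort against stromal cells is described. A source shared by same-numbered libraries would change its transcripts alike between them, but the labels do not say that they shared one. Over 15 markers at 1 FPKM or more in every CD73 library the log2 ratio of CD73-positive to CD73-negative cells ran from -0.74 to -0.11 (median -0.37, SD 0.129). A share of 6e-04 of 10000 random lists matched on expression had as small an SD (median SD 0.371). The small SD fits RNA of stromal cells carried over from the culture. Genes regulated together within the cells would give a small SD too, so it cannot decide between them. Markers did not keep 1 ratio between replicates: in CD73-negative libraries 1 and 2 Cxcl12 was 70.4 and 172, Col1a1 40.5 and 43.5, Cyr61 11.3 and 3.39 and Ctgf 2.01 and 0.259 FPKM. Shifts went in the same direction in CD73-positive libraries 1 and 2 (51.5 and 144, 32.4 and 32.8, 7.93 and 2.52 and 1.28 and 0.18). For expression set by the population itself, the DN3 libraries differed by a median log2 of 1.39, outside the -0.14 to 0.13 of 95% of random lists but below the 2.59 between CD73-negative and DN3 cells, so the values cannot tell it from a mixture. Carry-over could account for Col6a2 and Hp too, and differentiation of the population stays open, untested.

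Of 26 tested innate lymphoid and cytotoxic genes, with a median log2 fold change of 0.82 from CD73-negative to CD73-positive cells, 11 rose past the threshold (median 2.52 over these), and no gate against NK cells is described. Mature NK cells would bring all their abundant transcripts, and 9 such genes under 50 FPKM in CD73-negative cells, 6 of them among the 26, had a median of 0.84 (SD 0.694, range -0.0745 to 1.81), 3 of them past the threshold. In FPKM, Klrg1 from 0.532 to 3.37, Tbx21 from 1.2 to 6.72 and Itga2 from 2.23 to 9.8 rose past the threshold. The locus of Klra7 and other Klra genes from 0.881 to 2.7 (limma adjusted p 0.0688), Prf1 from 1.67 to 1.57 and Irf8 from 2.59 to 2.46 did not pass it. Nor did Ccl5 from 30.2 to 56.4, Eomes from 6.38 to 10.5 and Klrb1c from 1.83 to 3.68. Above 50 FPKM, Gzma went from 2360 to 2104 without passing, and Nkg7 rose past the threshold (log2 fold change 0.44 ± 0.07). Since only 2 of the 9, Ccl5 and Eomes, had 5 FPKM or more in CD73-negative cells, mature NK cells cannot be told apart from a change in expression. Cells without a TCR would lower the 3 CD3 chain genes, whose median was -0.38 with 0 past the threshold of limma (adjusted p 0.113, 0.146 and 0.237, with Cd3e and Cd3d at unadjusted p 0.0308 and 0.0477), so such cells stay open too. Innate lymphoid cells, and a programme of the committed gamma-delta cells, stay open, untested.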
